A study of Mus musculus with 23 samples.

How the data were processed

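Libraries came from macrophages sorted by flow cytometry, with 1000 cells collected into lysis buffer, primed with oligo-dT, amplified by PCR and tagmented, per the labels' protocols. STAR, edgeR and GRCm38 are named in the submitters' processing notes without versions or roles. The deposited values are normalised read counts, a signal scaled per library, in 1 table of 22524 genes with 12 libraries and 1 table of 25700 genes with 11 libraries. No header names the unit. It was read from the values: dividing each library by 1 factor gave whole reads (within 0.1 read, for values up to 500 reads) for 97.7 to 100% of values in the first table and 96.6 to 100% in the other. Recovered reads per library, in M, were 11.6 to 21.7 in RPM_d7_WT, 12.0 to 17.1 in RPM_d7_vavCre, 4.58 to 10.8 in BMM_d7_WT, 4.26 to 7.88 in BMM_d7_vavCre, 4.24 to 6.29 in RPM_d7_Spic_WT, 2.85 to 3.07 in RPM_d7_Spic_KO, 1.90 to 4.24 in RPM_TAM_WT and 0.693 to 1.67 in RPM_TAM_CreERT2. The values of a library sum to 9.14 to 10.5 M in the first table and 1.43 to 1.73 M in the other, so levels compare within a table only. No column was left unused. Of the genes, 22214 and 25587 have an identifier in GENCODE vM21, from which coordinates (1-based, GRCm38) were taken. The counting is not stated to use strand, so overlapping and antisense genes cannot be told apart, and near-identical paralogs may share reads.

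Groups came from the labels, which do not define TAM (read here as tamoxifen). Comparisons were vavCre against wild type in spleen and in marrow, the difference between these effects (interaction), spleen against marrow in wild type and in vavCre, Spic_KO against Spic_WT, and CreERT2 against wild type in adults. The design, the gene lists, the named-gene rule and the first alternatives were set before the data were examined. The design allowed a count test or limma. Because the tables hold normalised counts and not counts, its limma branch was used. Genes with a value of at least 1 in at least 2 libraries were tested, 15130 and 16650 in the 2 tables, after 5069 and 4321 genes at 0 in all libraries. Values were transformed as log2(value + 1), a pseudocount of 1 that understates the changes of low genes. limma 3.58.1 in R 4.3.3 fitted 1 mean per group to all libraries of a table (8 and 7 residual degrees of freedom), with an intensity trend and robust moderation (limma-trend). Benjamini-Hochberg adjusted p under 0.05 was a call, without a limit on the size of the change. Levels are means and SDs of the values, and log2 changes come from the log2 values.

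Gene lists numbered 27 and were written from general knowledge. They cover PPAR target genes, red pulp macrophage identity, iron and heme handling, efferocytosis and complement, macrophage genes and transcription factors, adhesion to erythroblasts, and markers of other blood and stromal cells. The rest cover cell cycle, interferon, inflammatory, immediate early, MHC class II, lysosome and metabolic genes. Each was tested with camera (correlation preset to 0.01, adjusted over the 27 lists), again with an estimated correlation, and with fry, which tests direction and not enrichment. Members were also counted past the threshold over all genes and adjusted over the list alone. Pparg and Spic are given in every comparison. Other named genes came from a rule. In each genotype comparison it took the 10 largest rises and 10 largest falls among called genes whose replicates did not overlap, with a mean of at least 20 in the higher group. It took 8 each way for the interaction and the wild-type tissue comparison. It added up to 4 passing members per list with the smallest p, or 2 with the highest mean where none passed. Predicted, ribosomal, mitochondrial, small RNA, immunoglobulin and T cell receptor segment, Xist and Y-linked genes were not ranked. The result of 1 gene that met the rule is not reported here, and counts of genes include it. Replicates of 3 against 3 libraries do not overlap by chance in 10% of genes. Folds against 0 reads use a floor of 3 reads per library, and genes with 1 to 3 reads carry a 95% counting interval. Shared calls were tested with Fisher's exact test, adjusted over 12 tests.

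Alternatives set in advance were no filter, a strict filter (10 in place of 1), pseudocounts of 0.1 and 5, an absolute log2 change of at least 1, the compared groups only, a replicate block, and leaving out each library in turn. Added later were edgeR 4.0.16 (quasi-likelihood, TMM or RLE factors), DESeq2 1.42.0 and limma-voom with quality weights on recovered reads, limma-trend with library weights, shared calls with each library left out in turn, and a fit without RPM_d7_Spic_KO replicate 2 and RPM_TAM_CreERT2 replicate 2. On recovered reads edgeR called 901 genes in splenic vavCre, 1064 in marrow vavCre, 29 in the interaction, 604 and 499 between tissues in wild type and vavCre, 809 in Spic_KO and 23 in CreERT2. The test was tested on simulated data with 100 genes changed per fold. It found 15 and 48 of 100 genes changed 2-fold and 4-fold in splenic vavCre, 18 and 62 in marrow vavCre, 3 and 41 in the interaction, 20 and 59 between wild-type tissues, 15 and 59 between vavCre tissues, 1 and 18 in Spic_KO, and 3 and 27 in CreERT2, with 1 to 7 false calls. Spic_KO and CreERT2 had 4 false calls each, a large share beside so few finds. The simulation gave all groups the same spread per gene. The real Spic_KO libraries correlated at 0.786 and the Spic_WT pairs at 0.948 to 0.962, so it may understate the spread in Spic_KO. Simulated shifted lists were found in 7 of 7 comparisons, and 1 of 7 unshifted lists had a camera p under 0.05 (0.0132). Simulated genes were drawn independently, while the estimated correlation of the interferon list in the vavCre libraries and their controls was 0.597. The simulation therefore does not test the preset correlation on real lists. Figures were drawn with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.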

Results

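Messenger RNA was sequenced from macrophages of C57BL/6 mice, with 1000 sorted cells collected per library. The 23 libraries fell into 8 groups. Macrophages of 7-day-old pups came from the spleen (RPM_d7, red pulp macrophages) and the bone marrow (BMM_d7). Each tissue had 3 wild-type and 3 vavCre libraries. vavCre names a Cre recombinase driven by the Vav gene, which acts in blood-forming cells. Spleen macrophages of day-7 pups with the genotype label Spic_KO, after the gene of the transcription factor SPIC (RPM_d7_Spic_KO, 2 libraries), had their own controls (RPM_d7_Spic_WT, 3 libraries). Adult spleen macrophages formed the groups RPM_TAM_CreERT2 (4 libraries) and RPM_TAM_WT (2 libraries). CreERT2 is a Cre that tamoxifen switches on. No label states the floxed gene, but the series describes the few remaining Pparg-deficient cells, and no label says whether replicates are separate animals. The vavCre libraries and their controls held 4262474 to 21744201 reads. Libraries of the other table held 692902 to 6289353. Levels below are normalised read counts (signal), given as mean ± SD, and compare within a table only.

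Pparg and Spic, the genes named by the series and the genotype labels, were read first. Pparg (ENSMUSG00000000440, chromosome 6, 115360951 to 115490399, plus strand, GRCm38) encodes a nuclear receptor that senses fatty acids. Its level was 1788 ± 299 in RPM_d7_WT (n = 3) and 3037 ± 838 in RPM_d7_vavCre (n = 3), a log2 change of 0.74 (limma adjusted p = 0.0313). That call was lost without RPM_d7_WT replicate 1 (0.11), RPM_d7_WT replicate 2 (0.144) or RPM_d7_vavCre replicate 1 (0.175). In marrow Pparg went from 1636 ± 57.8 to 2291 ± 606 (0.45, limma adjusted p = 0.193). Adult CreERT2 libraries held 229.7 ± 35.5 (n = 4) against 130.0 ± 53.4 (n = 2), which was no detectable difference (0.86, limma adjusted p = 0.600). Values summed over a gene cannot resolve a deleted exon, so these Pparg levels check no Cre label. Spic (ENSMUSG00000004359, chromosome 10, 88674772 to 88685015, minus strand) fell in RPM_d7_Spic_KO from 2435 ± 594 to 1084 ± 216 (-1.16, limma adjusted p = 0.0319). Reads remained in both knockout libraries, and the gene-level value does not show whether they come from the targeted part. The Spic call was lost without RPM_d7_Spic_WT replicate 1 (0.148), RPM_d7_Spic_WT replicate 3 (0.0726), RPM_d7_Spic_KO replicate 1 (0.115) or RPM_d7_Spic_KO replicate 2 (0.074), and over all alternatives its adjusted p ran from 0.00816 to 0.148.

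The first comparison asked how splenic macrophages differ in vavCre pups. The integrin gene Itgad (ENSMUSG00000070369, chromosome 7, 128154376 to 128223816, plus strand), a marker of red pulp macrophages, fell from 8923 ± 1114 in RPM_d7_WT to 128 ± 75.1 in RPM_d7_vavCre (n = 3 each; log2 change -6.35). Vcam1, whose product binds erythroblasts, fell from 59467 ± 4200.0 to 34543 ± 1666, and the haemoglobin scavenger receptor Cd163 from 2313 ± 542 to 689 ± 177. Spic fell from 14970 ± 1026 to 9259.7 ± 801, a log2 change of -0.69. In the other direction, the lectin gene Cd209f rose from 481 ± 173 to 39730 ± 3682, and the chemokine gene Ccl7 from 8.14 ± 5.40 to 924 ± 324. The scavenger receptor gene Stab1 rose by a log2 change of 5.22 and the chemokine gene Pf4 by 4.40. These changes exceeded the spread between replicates (limma adjusted p from 7.6e-13 for Stab1 to 0.00173 for Cd163), and each held when any 1 library was left out. Cd209f and Cd209g are close paralogs, so reads may be split between them.

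In the same libraries Fabp4, a fatty acid carrier and PPAR target, went from 133 ± 82.9 to 3.0 ± 1.69 (-4.97, limma adjusted p = 0.000630), and the fatty acid receptor Cd36 from 2755 ± 37.2 to 712 ± 127 (-1.96). Apoe and Abca1, 2 genes of lipid transport, rose, Apoe by 1.12 (limma adjusted p = 0.00233) and Abca1 by 1.07 (1.1e-05). The transcriptional regulator Id2 changed by -3.30 and the clearance receptor Axl by -1.88 on the log2 scale. Snx31, with 3 reads in all in the vavCre libraries, was 116 times lower (95% counting interval 40.6 to 575). Such intervals and floors cover counting error only, since PCR reads without molecular identifiers are not independent molecules. The chemokine gene Ccl2 went from 36.7 ± 20.4 to 1374 ± 474 and Cxcl10 from 432 ± 58.1 to 3526 ± 551. Lyz2 (lysozyme) rose by 1.99, the fractalkine receptor Cx3cr1 by 3.23 and the complement receptor C5ar1 by 5.05. In all, 451 of 15130 tested genes rose and 384 fell (limma-trend, adjusted p under 0.05), of which 264 and 282 changed by at least 1 log2 unit. The total of 835 dropped to 555 without RPM_d7_WT replicate 2 and to 536 without RPM_d7_vavCre replicate 2.

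**Figure D1:**
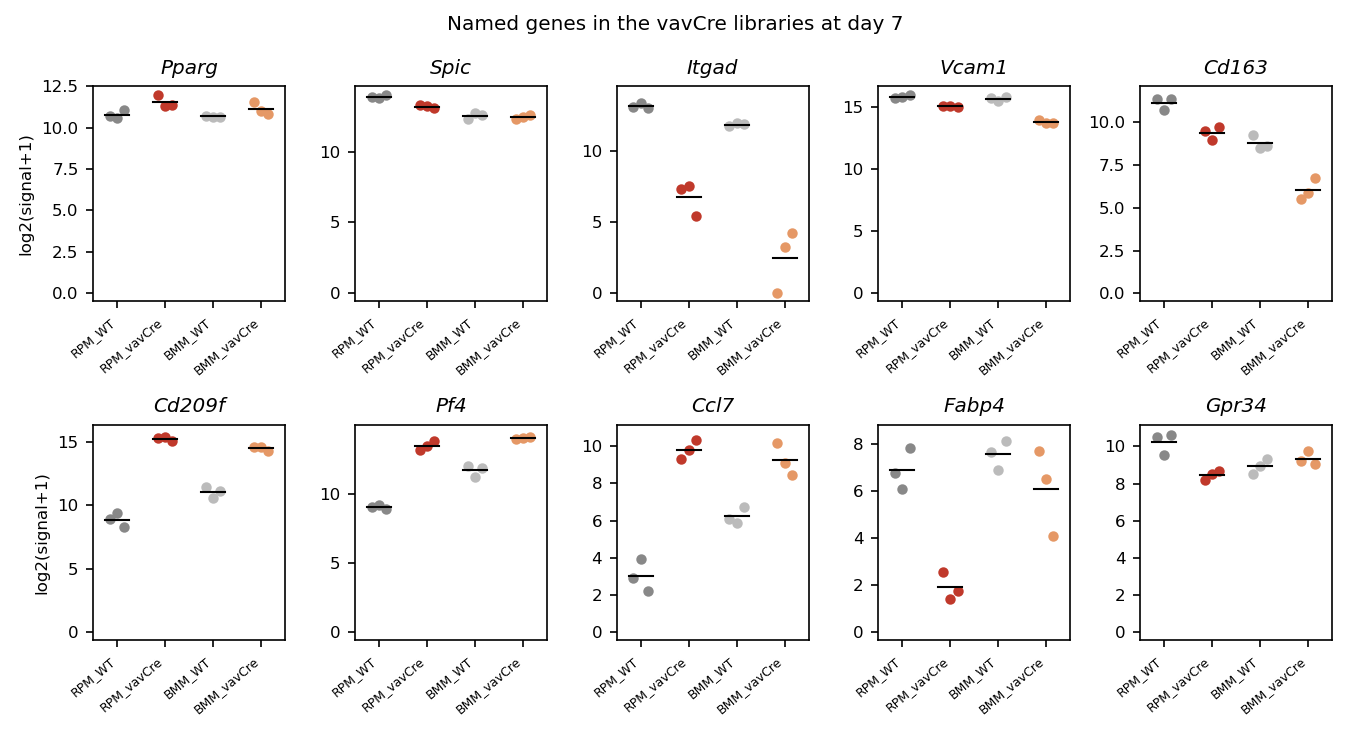
Each point is 1 library of the 4 day-7 groups with 3 libraries each, on a log2(signal + 1) axis, and each line is the mean of the log2 values. Itgad falls and Cd209f rises in the vavCre libraries of both tissues, while Pparg does not fall in either.

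The same question was asked in bone marrow, where the series names erythroblastic island macrophages. Itgad fell from 3666 ± 262 in BMM_d7_WT to 8.86 ± 9.06 in BMM_d7_vavCre (n = 3 each; -9.34, limma adjusted p = 9.4e-05). Vcam1 fell from 52973 ± 6051 to 14380 ± 1377 (-1.88), the sialoadhesin gene Siglec1 from 1022 ± 137 to 166 ± 56.4, and Cd163 from 450.1 ± 131 to 68.3 ± 31.6. Epor, the erythropoietin receptor gene, fell from 1306 ± 57.1 to 397 ± 78.5. Ubd had 0 reads in the 3 vavCre libraries against 149 ± 51.8 in wild type, at least 26.7-fold lower at a floor of 3 reads per library. The organic anion transporter gene Slco2b1 changed by -6.60 and Vstm4 by -7.90 on the log2 scale. Gpnmb, a lysosomal glycoprotein gene, rose to 392.4 ± 184 from 1 read in all, a ratio of 585 (95% counting interval 161 to 35471). Stab1 rose from 1046 ± 46.4 to 9620 ± 1296, the endothelin receptor gene Ednrb by 5.43, and Pf4 by 2.34. Spic did not differ detectably, with 5957 ± 881 in wild type and 5524 ± 646 in vavCre (-0.10, limma adjusted p = 0.705). In total 516 genes rose and 666 fell of 15130 (limma-trend), 301 and 529 of them by at least 1 log2 unit, and the named changes other than Spic held when any 1 library was left out.

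Groups of genes gave the next view of both vavCre comparisons. The list of 16 red pulp macrophage identity genes shifted downward as a whole. Its median was -0.97 in spleen, where 9 members fell and 1 rose over all genes tested (10 and 1 adjusted over the list alone; camera adjusted p = 8.1e-11). In marrow its median was -2.03, with 9 falling and 2 rising (10 and 2 adjusted over the list alone; camera adjusted p = 9.9e-12). Genes for adhesion to erythroblasts fell in both tissues, with medians of -0.74 and -0.60 (6 and 7 of 12 members fell, 8 and 7 adjusted over the list alone, where 1 also rose in spleen). Their camera adjusted p was 1.6e-06 in spleen and 3.2e-06 in marrow. Pan-macrophage genes such as Lyz2 and Maf rose, with medians of 0.38 and 0.38 (6 of 16 rose in each tissue, 9 and 7 adjusted over the list alone; 1 fell in marrow, and 1 in each tissue adjusted over the list alone). Inflammatory cytokines and NF-kB targets such as Ccl2, Ccl3 and Ccl4 rose by medians of 0.96 and 0.70, with 6 of 19 members rising in each tissue (8 and 6 adjusted over the list alone; 1 fell in marrow, and 1 in each tissue adjusted over the list alone). With an estimated correlation these 4 lists and the erythroid list kept their calls in both tissues (camera), the highest adjusted p being 0.0415.

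Erythroid genes were lower in the vavCre libraries of both tissues. The alpha and beta globin genes together took 2.79 ± 0.631% of signal in RPM_d7_WT and 1.21 ± 0.241% in RPM_d7_vavCre, and 2.86 ± 0.586% in BMM_d7_WT and 1.12 ± 0.219% in BMM_d7_vavCre (n = 3 each). Hbb-bt, whose reads overlap those of its near copy Hbb-bs, changed by -1.12 and -1.28 on the log2 scale, Car2 by -1.24 and -1.42, and Rhag by -1.38 and -1.78 in spleen and marrow. The median of the 20 tested erythroid markers was -1.27 and -1.51, with 13 and 17 members falling (17 and 18 adjusted over the list alone; camera adjusted p = 3.9e-18 and 1.3e-19). Epb42 and Ahsp, 2 members of that list, were absent from the table, as was Flvcr1 of the iron list. Cell cycle genes such as Mki67 (-0.96 and -0.93) and Top2a (-1.11 and -1.20) fell beside them. The cell cycle medians were -0.80 and -0.89, 12 of 27 members falling in each tissue (20 and 19 adjusted over the list alone, where 1 rose in marrow; camera adjusted p = 1.4e-15 and 9.9e-12, but 0.0620 and 0.106 with an estimated correlation).

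Several further lists passed with the preset correlation only. Lysosomal genes such as Grn rose slightly, by medians of 0.25 in spleen and 0.20 in marrow (9 up and 0 down of 25, 12 and 1 adjusted over the list alone, and 9 up and 0 down of 25, 9 and 1 adjusted over the list alone; camera adjusted p = 5.4e-06 and 3.2e-06, but 0.220 and 0.229 with an estimated correlation). Interferon response genes, Cxcl10 and Bst2 among them, had medians of 0.59 and 0.85 (4 up and 0 down of 20, 6 and 0 adjusted over the list alone, and 2 up and 0 down of 20, 2 and 0 adjusted over the list alone; 9.1e-05 and 0.000448 by camera, 0.440 and 0.572 with an estimated correlation). Their mean log2 levels per library overlapped between genotypes. In spleen they were 7.62 to 8.79 in wild type and 8.08 to 9.43 in vavCre, and in marrow 7.23 to 8.11 and 7.57 to 9.05. MHC class II genes had a median of -0.99 in spleen (0 up and 0 down of 10, 0 and 0 adjusted over the list alone) and -2.41 in marrow (0 up and 6 down of 10, 0 and 7 adjusted over the list alone; camera adjusted p = 0.00754 and 7.1e-07, 0.359 and 0.0905 with an estimated correlation), and the splenic call was lost without RPM_d7_vavCre replicate 3 (0.225). Eosinophil and mast cell genes, led by Ear2, changed by -1.58 in spleen (0 up and 2 down of 11, 0 and 3 adjusted over the list alone) and -0.49 in marrow (0 up and 2 down of 11, 0 and 2 adjusted over the list alone). Their camera adjusted p was 0.00326 and 0.0390 (0.0768 and 0.229 with an estimated correlation), and the marrow call was lost without BMM_d7_WT replicate 2 (0.201), BMM_d7_WT replicate 3 (0.0623) or BMM_d7_vavCre replicate 3 (0.238). Neutrophil genes in spleen had a median of 2.40 (2 up and 0 down of 16, 3 and 0 adjusted over the list alone; camera adjusted p = 0.000327, 0.200 with an estimated correlation). Efferocytosis and complement genes in spleen had a median of -0.07 but a mean of 0.49, since Stab1, Marco and Gas6 rose while Axl and Cd36 fell (8 up and 3 down of 25, 10 and 6 adjusted over the list alone; camera, upward, adjusted p = 0.00865, 0.0768 with an estimated correlation).

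The next 3 lists passed in marrow and not in spleen. B cell genes fell, with a median of -1.85 (0 up and 3 down of 12, 0 and 3 adjusted over the list alone; camera adjusted p = 0.00516, 0.463 with an estimated correlation, and 0.0508 without BMM_d7_WT replicate 2). T and NK cell genes had a median of -2.33 (0 up and 0 down of 13, 0 and 0 adjusted over the list alone; camera adjusted p = 0.0297, 0.572 with an estimated correlation). That call was lost without BMM_d7_WT replicate 2 (0.0988), BMM_d7_WT replicate 3 (0.149), BMM_d7_vavCre replicate 1 (0.105) or BMM_d7_vavCre replicate 3 (0.260). Glycolysis and hypoxia genes had a median of 0.32 (2 up and 1 down of 20, 2 and 1 adjusted over the list alone; camera adjusted p = 0.0390, 0.573 with an estimated correlation), a call lost without BMM_d7_WT replicate 1 (0.193), BMM_d7_WT replicate 3 (0.227) or BMM_d7_vavCre replicate 1 (0.232). For T and NK cell genes and for glycolysis the difference between tissues did not pass (camera adjusted p = 0.250 and 0.286), so these 2 calls set no tissue apart. The 12 lists that passed in neither vavCre comparison were PPAR target genes, iron and heme handling, macrophage transcription factors, monocyte, dendritic, endothelial and stromal, and megakaryocyte markers, immediate early genes, fatty acid oxidation, oxidative phosphorylation, LXR targets and cholesterol synthesis. Of these, fatty acid oxidation in spleen came closest (camera adjusted p = 0.0530).

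**Figure D2:**
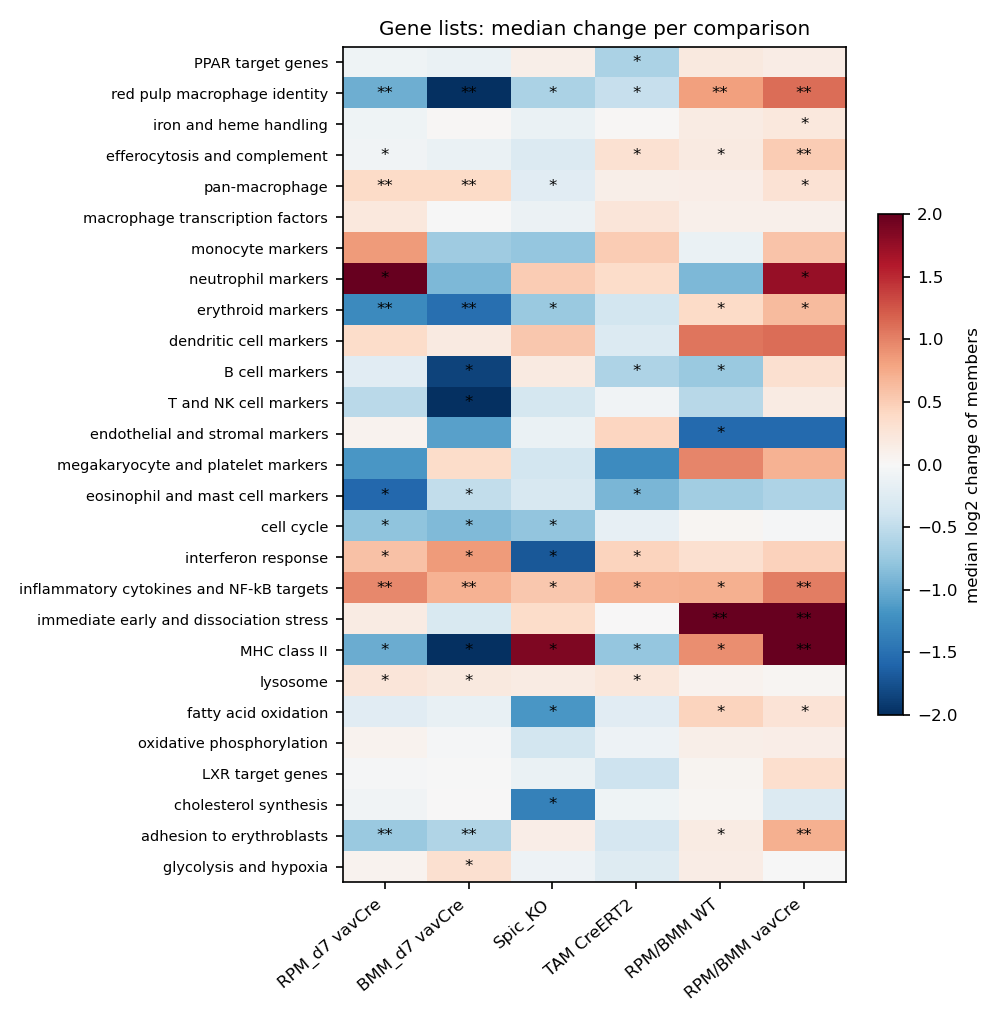
Colour gives the median log2 change of the tested members of each of 27 gene lists in 6 comparisons, with colours ending at 2 in either direction; 1 asterisk marks a camera call with the preset correlation and a pair of asterisks a call kept with an estimated correlation. Erythroid markers and red pulp macrophage identity genes have negative medians in both vavCre comparisons, and red pulp macrophage identity genes also in the Spic_KO and CreERT2 comparisons.

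Whether vavCre acts differently in spleen and marrow was tested as an interaction. Cd209f rose by 6.43 log2 units in spleen and by 3.46 in marrow, a difference of 2.97 (limma adjusted p = 0.000482), from lower wild-type levels in spleen (481 ± 173) than in marrow (2191 ± 622). Pf4 differed by 2.05, Stab1 by 2.03 and Cd209g by 2.52, each rising more in spleen. In wild type Pf4 and Stab1 were also lower in spleen than in marrow, so their splenic rises started from lower levels. Vcam1 fell less in spleen (difference 1.10). Timd4, a receptor for dying cells, went opposite ways. It rose from 2848 ± 326 to 5618 ± 703 in spleen and fell from 3935 ± 196 to 2133 ± 804 in marrow (difference 1.93, limma adjusted p = 0.00259). Each of these 6 differences held when any 1 library was left out. Neither Pparg (0.29, limma adjusted p = 0.914) nor Spic (-0.59, 0.415) passed. In all 17 genes had a higher log2 change in spleen and 1 a lower one (limma-trend), and the 18 became 11 without RPM_d7_WT replicate 1 or without BMM_d7_vavCre replicate 1. With DESeq2 on recovered reads 76 were higher and 30 lower, so the share higher in spleen depends on the test.

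**Figure D3:**
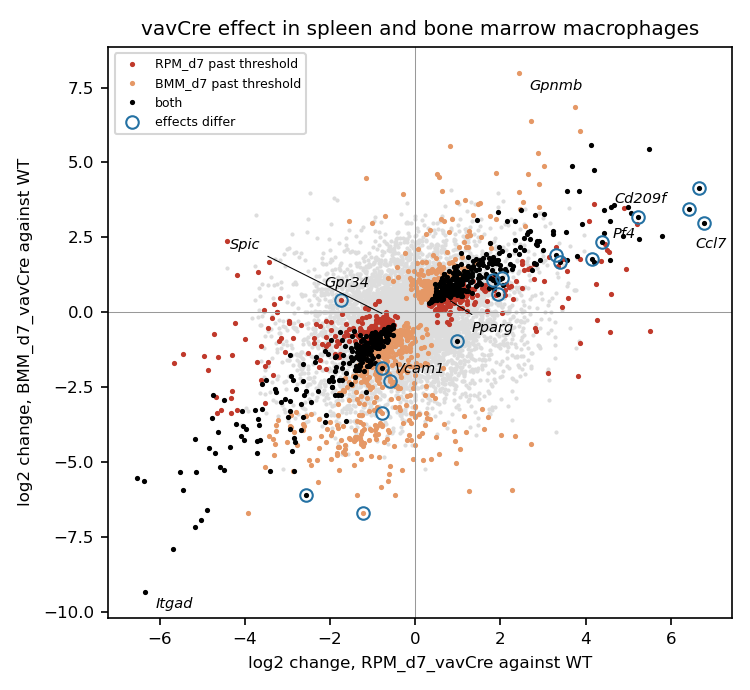
Each point is 1 of 15130 genes, with its log2 change in splenic vavCre macrophages on the x axis and in marrow vavCre macrophages on the y axis; coloured and black points passed adjusted p under 0.05 and circles mark the 18 genes whose effects differ. Most genes past the threshold lie in the lower left and upper right of the plot, with Itgad at the lowest marrow value.

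Among the lists, red pulp macrophage identity genes had a higher log2 change in spleen than in marrow (median difference 0.82, camera adjusted p = 0.000304), with Vcam1 the member past the threshold over all genes. Efferocytosis and complement genes, including Stab1 and Timd4, differed by 0.20 (2 up and 0 down of 25, 5 and 0 adjusted over the list alone; 0.00172). Neutrophil genes had a median difference of 2.75 (0 up and 0 down of 16, 2 and 0 adjusted over the list alone; 0.000122). B cell genes had a median difference of 1.24 (0 up and 0 down of 12, 2 and 0 adjusted over the list alone; 0.00172, and 0.0689 without RPM_d7_WT replicate 1). Immediate early genes had a median difference of 0.69 (0 up and 0 down of 20, 0 and 0 adjusted over the list alone; 0.00172, 0.053 without RPM_d7_WT replicate 1 and 0.0629 without BMM_d7_WT replicate 1). MHC class II genes had a median difference of 0.94 (0 up and 0 down of 10, 0 and 0 adjusted over the list alone; 0.00291, 0.0583 without RPM_d7_vavCre replicate 1 and 0.0801 without BMM_d7_WT replicate 2). With an estimated correlation 0 of the 27 lists passed by camera, the lowest adjusted p being 0.0770, and fry, which is directional and not competitive, called 2. The remaining 21 lists did not pass.

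The wild-type libraries gave the difference between tissues. Spic was higher in spleen, at 14970 ± 1026 against 5957 ± 881 in marrow (n = 3 each; 1.34, limma adjusted p = 1.9e-06), while Pparg did not differ detectably (0.12, 0.840). The chemokine receptor gene Ccr3 was 9163 ± 695 in spleen and 884 ± 238 in marrow, Treml4 5324 ± 928 and 1009 ± 105, and Cd163 2313 ± 542 and 450.1 ± 131. Hs3st2, a heparan sulfate enzyme gene, was 669.7 ± 146 in spleen and 7.69 ± 4.76 in marrow. Higher in marrow were Pf4 (-2.64), Stab1 (-2.39) and Trem2 (-4.78). The B cell progenitor genes Igll1 (-7.66) and Rag1 (1 read in all in spleen, a ratio of 447, 95% counting interval 77.0 to 16937) were also higher in marrow. Immediate early genes, which respond within minutes to tissue dissociation, were higher in spleen by a median of 2.05 (13 of 20 members, 15 adjusted over the list alone; camera adjusted p = 4.2e-21, 0.0189 with an estimated correlation), for example Dusp1 (3.77) and Egr1 (3.23). In total 313 genes were higher in spleen and 275 in marrow (limma-trend, 15130 tested). The total of 588 became 333 without RPM_d7_WT replicate 1, 269 without RPM_d7_WT replicate 3, 305 without BMM_d7_WT replicate 1 and 315 without BMM_d7_WT replicate 3.

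Red pulp macrophage identity genes were higher in wild-type spleen by a median of 0.81 (8 up and 0 down of 16, 8 and 0 adjusted over the list alone; camera adjusted p = 3.2e-09, 0.00604 with an estimated correlation). Fatty acid oxidation (0.44, 4 up and 0 down of 20, 5 and 0 adjusted over the list alone, 5.2e-05), inflammatory cytokine (0.71, 3 up and 1 down of 19, 9 and 1 adjusted over the list alone, 0.00497), MHC class II (0.93, 2 up and 0 down of 10, 3 and 0 adjusted over the list alone, 0.00799) and erythroblast adhesion genes (0.16, 3 up and 0 down of 12, 4 and 1 adjusted over the list alone, 0.00999) were also higher in spleen by camera with the preset correlation only. So were efferocytosis and complement genes (0.19, 4 up and 1 down of 25, 8 and 2 adjusted over the list alone, 0.0277), a call lost without RPM_d7_WT replicate 1 (0.0572), RPM_d7_WT replicate 3 (0.0523) or BMM_d7_WT replicate 3 (0.054). Erythroid genes had a median of 0.39 with no member past the threshold (0 up and 0 down of 20, 0 and 0 adjusted over the list alone; camera adjusted p = 0.0352), a call lost without RPM_d7_WT replicate 1 (0.132), RPM_d7_WT replicate 2 (0.176), BMM_d7_WT replicate 2 (0.333) or BMM_d7_WT replicate 3 (0.0794). B cell genes had a median of -0.74 (1 up and 1 down of 12, 1 and 3 adjusted over the list alone; 0.0436), lost without RPM_d7_WT replicate 1 (0.377), RPM_d7_WT replicate 2 (0.0646), BMM_d7_WT replicate 2 (0.333) or BMM_d7_WT replicate 3 (0.0794). Endothelial and stromal genes had a median of -1.55 (1 up and 1 down of 13, 1 and 3 adjusted over the list alone; 0.0238), lost without RPM_d7_WT replicate 1 (0.0551), RPM_d7_WT replicate 2 (0.0772), BMM_d7_WT replicate 1 (0.0836) or BMM_d7_WT replicate 3 (0.0506). With an estimated correlation these 3 lists had camera adjusted p of 0.523, 0.523 and 0.218. The remaining 17 lists did not pass.

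In the vavCre libraries the tissues also differed. Spic was 9259.7 ± 801 in spleen and 5524 ± 646 in marrow (0.75, limma adjusted p = 0.00108), and Pparg did not differ detectably (0.40, 0.314). Vcam1 was 34543 ± 1666 in spleen and 14380 ± 1377 in marrow (1.27), Cd163 689 ± 177 and 68.3 ± 31.6, and the eosinophil-associated gene Ear2, one of a family of similar genes, 578 ± 44.9 and 39.3 ± 36.9. Cxcl2 had 0 reads in marrow, at least 21.4-fold lower than in spleen. In all 405 genes were higher in spleen and 124 in marrow (limma-trend), 76.6% higher in spleen, against 615 and 393 with DESeq2 and 301 and 156 with limma-voom on recovered reads. The total of 529 became 271 without RPM_d7_vavCre replicate 1, 339 without RPM_d7_vavCre replicate 2 and 317 without RPM_d7_vavCre replicate 3. Higher in spleen with either correlation (camera) were red pulp macrophage identity (median 1.11, adjusted p = 3.8e-20), immediate early (3.0, 4.3e-29) and MHC class II genes (2.38, 1.4e-08). Efferocytosis (0.50, 2.3e-08), inflammatory cytokine (1.03, 3.2e-05) and erythroblast adhesion genes (0.71, 3.7e-05) were higher with either as well. With the preset correlation only, erythroid genes (0.63, 5 up and 0 down of 20, 9 and 0 adjusted over the list alone, 3.2e-05), fatty acid oxidation genes (0.27, 1 up and 0 down of 20, 3 and 0 adjusted over the list alone, 0.000719) and iron genes (0.21, 6 up and 0 down of 27, 10 and 2 adjusted over the list alone, 0.00898, 0.0505 without BMM_d7_vavCre replicate 3) passed. Pan-macrophage genes (0.28, 6 up and 1 down of 16, 7 and 2 adjusted over the list alone, 0.0156, 0.0734 without BMM_d7_vavCre replicate 2) and neutrophil genes (1.75, 1 up and 0 down of 16, 1 and 0 adjusted over the list alone, 0.0156) did so too. The neutrophil call was lost without RPM_d7_vavCre replicate 1 (0.0655), RPM_d7_vavCre replicate 3 (0.0623), BMM_d7_vavCre replicate 2 (0.0734) or BMM_d7_vavCre replicate 3 (0.0549). The remaining 16 lists did not pass.

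The Spic_KO comparison asked how red pulp macrophages with that label differ at day 7. Pparg fell from 254 ± 66.3 in RPM_d7_Spic_WT (n = 3) to 23.9 ± 3.04 in RPM_d7_Spic_KO (n = 2; -3.33, limma adjusted p = 2.9e-05). Itgad fell from 1805 ± 314 to 3.86 ± 4.05 (-8.83) and Ccr3 from 1358 ± 296 to 5.04 ± 4.20 (-7.99). The protease inhibitor gene Slpi (ENSMUSG00000017002, chromosome 2, 164354070 to 164389095, minus strand) had 0 reads against 351 ± 152, at least 230-fold lower. Vcam1 fell from 7626 ± 378 to 2716 ± 308. Hmox1 (heme oxygenase) fell from 5136 ± 3179 to 1325 ± 53.7, the biliverdin reductase gene Blvrb from 2196 ± 116 to 581 ± 80.9, and the ferritin gene Ftl1 with a log2 change of -1.12, while the iron and heme handling list as a whole did not pass (0 up and 6 down of 28, 2 and 6 adjusted over the list alone; camera adjusted p = 0.245). The Spic_WT mean of Hmox1 rested largely on replicate 1, at 8806 against 3227 and 3374 in replicates 2 and 3. The antigen presentation genes H2-Ab1 and H2-Aa rose, H2-Ab1 from 168 ± 119 to 2066 ± 194 (3.82) and H2-Aa by 3.64. Pf4 rose from 75.2 ± 27.5 to 1292 ± 342 and Rab7b by 7.69. The transcription factor gene Tox2 rose from 0 reads to 192 ± 21, at least 207-fold higher. All of these gene calls held when any 1 library was left out, by limma-trend, where a lone library left in a group is assumed to vary like the others.

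**Figure D4:**
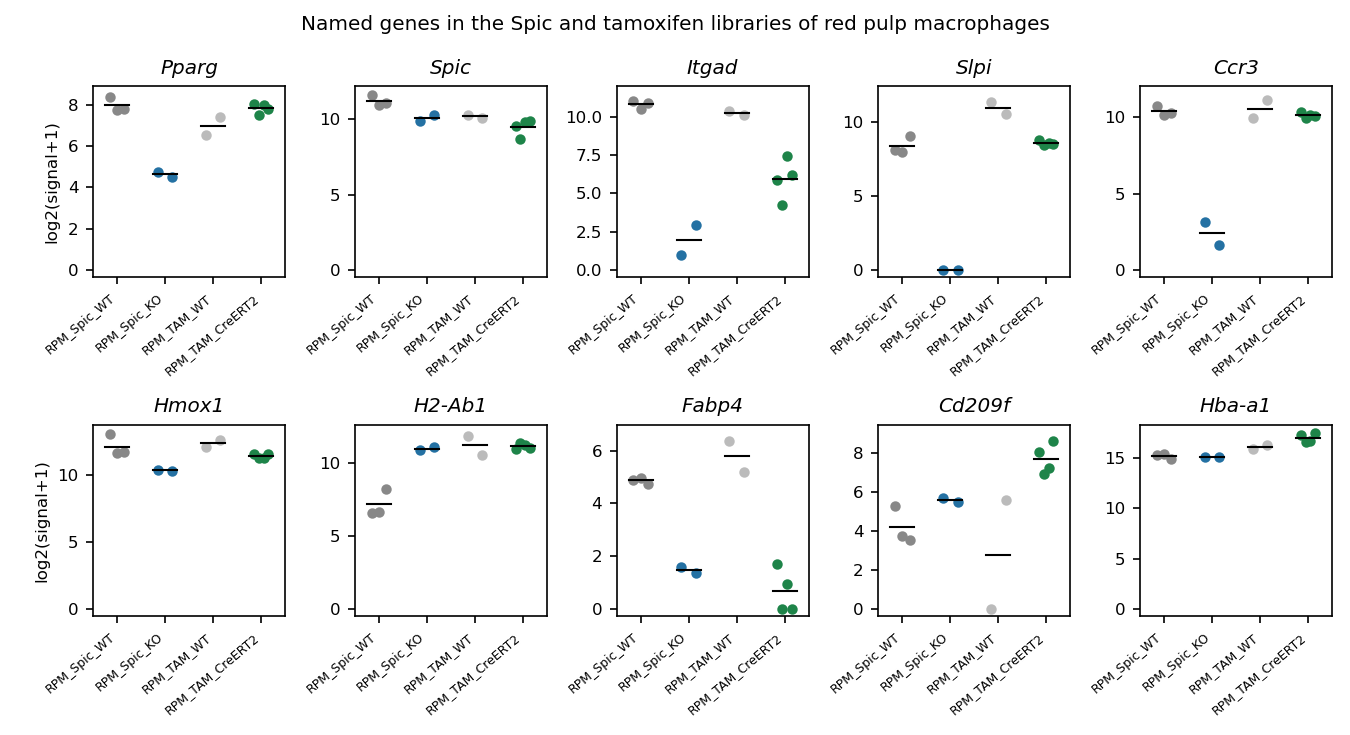
Each point is 1 library of the Spic and tamoxifen groups (3, 2, 2 and 4 libraries from left to right), on a log2(signal + 1) axis, and each line is the mean of the log2 values. Pparg falls in the Spic_KO libraries and not in the CreERT2 libraries, and Itgad falls in both.

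The size of the Spic_KO response rested on single libraries. Calls were 245 genes up and 413 down of 16650 (limma-trend), and 239 and 406 of them changed by at least 1 log2 unit. The total of 658 became 261 without RPM_d7_Spic_WT replicate 1, 355 without RPM_d7_Spic_WT replicate 2 and 316 without RPM_d7_Spic_WT replicate 3. It became 1972 without RPM_d7_Spic_KO replicate 1 and 297 without RPM_d7_Spic_KO replicate 2. The share that rose, 37.2%, also depended on the test: edgeR on recovered reads called 440 up and 369 down (523 and 369 with RLE factors), DESeq2 977 and 857, and limma-voom with quality weights 277 and 62. These tests differ in input, weights and scaling together. Over the 12939 genes shared with limma-trend (12916 for DESeq2), the median of the per-gene differences in log2 change was 0.12 with RLE factors and with DESeq2, and 0.01 with limma-voom. Spic, Pparg, Itgad, Ccr3 and Pf4 kept their direction under these tests. Satellite-like predicted genes such as Gm10801 took 0.525 and 2.10% of signal in the Spic_KO libraries and 0.00893 to 0.0485% in Spic_WT, and reads at equal depth lay in 68 and 138 against 16 to 26 olfactory receptor genes. Olfr656, a gene of that family, had a signal of 0 in every Spic_WT library and of 52.6 and 150 in the Spic_KO libraries.

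Lists in the Spic_KO comparison passed with the preset correlation only, and 0 of 27 passed by camera with an estimated one (lowest adjusted p = 0.0887). Interferon response genes such as Ifit3 fell, with a median of -1.69 (8 of 20 members, 12 adjusted over the list alone; camera adjusted p = 2.7e-08). MHC class II genes rose by 1.86 (4 of 10, 7 adjusted over the list alone; 6.0e-08), opposite in sign to the medians of both vavCre comparisons. Red pulp macrophage identity genes changed by -0.63 (6 of 16, 9 adjusted over the list alone; 2.4e-06) and cell cycle genes by -0.79 (0 up and 1 down of 27, 0 and 3 adjusted over the list alone; 0.00210). The 6 falling identity genes include Spic itself, the gene of the knockout label. Fatty acid oxidation genes changed by -1.16 (0 up and 2 down of 20, 0 and 3 adjusted over the list alone; 0.00461) and pan-macrophage genes by -0.23 (0 up and 4 down of 16, 0 and 6 adjusted over the list alone; 0.00854), calls lost without RPM_d7_Spic_KO replicate 1 (0.0636 and 0.0778). Cholesterol synthesis genes changed by -1.34 (0 up and 2 down of 18, 0 and 3 adjusted over the list alone; 0.0384), lost without RPM_d7_Spic_WT replicate 2 (0.0621) or RPM_d7_Spic_KO replicate 2 (0.179). Erythroid genes changed by -0.74 (1 up and 3 down of 21, 1 and 5 adjusted over the list alone; 0.0384), lost without RPM_d7_Spic_WT replicate 2 (0.118) or RPM_d7_Spic_KO replicate 1 (0.310), while haemoglobin genes took 6.15 ± 1.06% of signal in Spic_WT and 5.18 ± 0.246% in Spic_KO. Inflammatory cytokine genes had a median of 0.54 (1 up and 0 down of 19, 2 and 0 adjusted over the list alone; 0.0445), lost without RPM_d7_Spic_WT replicate 2 (0.0600) or RPM_d7_Spic_WT replicate 3 (0.0763). Their mean log2 level was 5.54 in RPM_d7_Spic_KO replicate 2 but 4.51 in replicate 1, against 4.12 to 4.41 in Spic_WT, so replicate 2 carried most of the shift. The remaining 18 lists did not pass.

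The adult comparison asked what an induced CreERT2 changes in mature red pulp macrophages. Dab2 (ENSMUSG00000022150, chromosome 15, 6299788 to 6440712, plus strand), an endocytosis adaptor gene, rose from 5.89 ± 1.4 in RPM_TAM_WT (n = 2) to 132 ± 62.2 in RPM_TAM_CreERT2 (n = 4; 4.16, limma adjusted p = 0.000209) and held when any 1 library was left out. Itgad fell from 1208 ± 182 to 79.9 ± 66.2 (-4.30), a call lost without RPM_TAM_WT replicate 1 (0.183) or RPM_TAM_WT replicate 3 (0.0555). Slpi fell from 2046 ± 815 to 379.8 ± 36.5 and the signalling adaptor gene Sh2d1b1 from 155 ± 13.5 to 15.3 ± 4.86, and both calls were lost without RPM_TAM_WT replicate 1 (0.296 and 0.166). The alpha globin gene Hba-a2, whose reads overlap those of its copy Hba-a1, rose from 45355 ± 658 to 119075 ± 33276 and was lost without RPM_TAM_WT replicate 1 (0.166). Haemoglobin genes took 9.17 ± 2.45% of signal in TAM_WT and 16.5 ± 3.70% in CreERT2. Reads at equal depth lay in 90 to 202 olfactory receptor genes in CreERT2 and in 26 and 89 in TAM_WT. Spic did not change detectably, at 1176 ± 98.3 and 762 ± 243 (-0.69, limma adjusted p = 0.579). Fabp4 had 3 reads in the 4 CreERT2 libraries, 73.4 times lower than in TAM_WT (95% counting interval 19.3 to 273), and its call (limma adjusted p = 0.0432) was lost when any 1 library was left out (0.0633 to 0.439). In all 10 genes rose and 14 fell of 16650 (limma-trend), 8 and 14 of them by at least 1 log2 unit, and 1244 had an unadjusted p under 0.05. The 24 became 2 without RPM_TAM_WT replicate 1, 5 without RPM_TAM_CreERT2 replicate 1, 6 without RPM_TAM_CreERT2 replicate 2 or replicate 5, and 11 without RPM_TAM_CreERT2 replicate 4. Without RPM_TAM_WT replicate 3 there were 18, of which 13 rose, and edgeR on recovered reads called 6 up and 17 down (6 and 14 with RLE factors).

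Lists in adults again passed with the preset correlation only, 0 of 27 passing by camera with an estimated one (lowest adjusted p = 0.263). In each of these 9 lists at most 1 member passed over all genes. Red pulp macrophage identity genes had a median of -0.46 (0 up and 1 down of 16, 0 and 3 adjusted over the list alone; camera adjusted p = 0.000113) and B cell genes of -0.61 (0 up and 0 down of 12, 0 and 1 adjusted over the list alone; 0.00505). MHC class II genes had a median of -0.77 (0 up and 0 down of 10, 0 and 1 adjusted over the list alone; 0.00453, 0.298 without RPM_TAM_WT replicate 1). PPAR target genes such as Fabp4 had a median of -0.63 (0 up and 1 down of 20, 0 and 1 adjusted over the list alone; 0.0342), lost without RPM_TAM_WT replicate 3 (0.219), RPM_TAM_CreERT2 replicate 1 (0.0881), RPM_TAM_CreERT2 replicate 2 (0.0542) or RPM_TAM_CreERT2 replicate 4 (0.0638). Lysosomal genes had a median of 0.22 (1 up and 0 down of 24, 1 and 0 adjusted over the list alone; 0.0134), lost without RPM_TAM_WT replicate 1 (0.747) or RPM_TAM_CreERT2 replicate 1 (0.0646). Efferocytosis genes had a median of 0.30 (1 up and 0 down of 25, 3 and 2 adjusted over the list alone; 0.0342), lost without RPM_TAM_WT replicate 1 (0.351), RPM_TAM_CreERT2 replicate 1 (0.0976) or RPM_TAM_CreERT2 replicate 5 (0.0703). Interferon genes had a median of 0.45 (0 up and 0 down of 20, 0 and 0 adjusted over the list alone; 0.0342), lost without RPM_TAM_WT replicate 1 (0.392), RPM_TAM_CreERT2 replicate 1 (0.0881) or RPM_TAM_CreERT2 replicate 4 (0.0937). Inflammatory genes had a median of 0.69 (0 up and 0 down of 19, 1 and 0 adjusted over the list alone; 0.0342), lost without RPM_TAM_WT replicate 3 (0.593, where the direction reversed), RPM_TAM_CreERT2 replicate 1 (0.0881) or RPM_TAM_CreERT2 replicate 4 (0.0923). Eosinophil and mast cell genes had a median of -0.92 (0 up and 0 down of 11, 0 and 0 adjusted over the list alone; 0.0342), lost without RPM_TAM_WT replicate 1 (0.392), RPM_TAM_CreERT2 replicate 1 (0.0976) or RPM_TAM_CreERT2 replicate 4 (0.0759). The remaining 18 lists did not pass.

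Calls were compared between the 4 genotype comparisons, which share no libraries. Itgad, Slpi, Txn1, Cox6a2 and Glipr1 fell in all 4, but without RPM_TAM_WT replicate 1 all 5 lost the CreERT2 call (limma adjusted p from 0.183 for Itgad to 0.616 for Glipr1). Txn1, Cox6a2 and Glipr1 lost it with each of the other 5 libraries of that comparison left out as well, and Itgad without RPM_TAM_WT replicate 3 (0.0555). Cox6a2 (chromosome 7, 128205435 to 128206387, minus strand) lies inside Itgad on the other strand. The counting is not stated to use strand, so the falls of Itgad and Cox6a2 may not be separate. Slpi lost its marrow call without BMM_d7_WT replicate 2 (0.0766). Txn1 lost its Spic_KO call without 3 of the 5 libraries and Glipr1 without 4. Dab2, Gas6, Grn and Cd209f rose in both vavCre comparisons and in CreERT2, though in CreERT2 only Dab2 held without RPM_TAM_WT replicate 1 or without any 1 CreERT2 library. Pf4, Cx3cr1, C5ar1 and Tox2 rose in both vavCre comparisons and in Spic_KO. Spleen and marrow vavCre shared 284 genes that rose and 233 that fell, where independent lists would share 15.4 and 16.9, and 1 gene went opposite ways. Across genes, which are not independent replicates, their log2 changes correlated at r = 0.39. Splenic vavCre and Spic_KO shared 45 that rose and 83 that fell (7.13 and 11.1 by chance), with 25 of the genes that rose in vavCre falling in Spic_KO and 3 the other way. Marrow vavCre and Spic_KO shared 38 and 77 (8.18 and 18.9 by chance), with 23 of the genes that rose in vavCre falling in Spic_KO and 11 the other way. No chance count was computed for opposite calls, so the counts do not show whether these also exceed chance. An excess of shared rising genes alone therefore does not establish a response in 1 direction. The log2 changes in Spic_KO correlated at r = 0.18 with splenic and 0.11 with marrow vavCre. Of the genes that rose in splenic and marrow vavCre, 57.2 and 52.1% had the same sign in Spic_KO, against 81.6 and 72.9% of those that fell. CreERT2 shared 5 rising and 8 falling genes with splenic vavCre (0.257 and 0.360 by chance), 4 and 8 with marrow vavCre (0.295 and 0.613) and 2 and 6 with Spic_KO (0.147 and 0.347). Of the genes that rose in each of these 3 comparisons 0 fell in CreERT2, and of those that fell 2, 3 and 0 rose in CreERT2. All 12 overlaps, 1 for each direction of 6 pairs, passed Fisher's exact test (largest adjusted p = 0.00898). Without RPM_TAM_WT replicate 1 only the 6 without CreERT2 passed, and CreERT2 then shared 1 rising and 0 falling genes with each vavCre comparison and 0 of either with Spic_KO. Over the 23 fits with 1 library left out, the rising overlaps of CreERT2 passed in 16 with splenic vavCre, 15 with marrow vavCre and 17 with Spic_KO, and the falling ones in 22, 22 and 21. The shared rising genes dropped to 1 in both vavCre comparisons, and those overlaps failed, without any 1 CreERT2 library (adjusted p from 0.0699 to 0.140), RPM_d7_Spic_WT replicate 1 (0.0762 and 0.0793) or RPM_d7_Spic_WT replicate 2 (0.0693 and 0.0726). The Spic_WT libraries are part of the same fit, and leaving out RPM_d7_Spic_WT replicate 3 ended the marrow overlap as well (0.117). The 6 overlaps without CreERT2 passed in all 23 fits (largest adjusted p = 0.000103), but their sizes moved. Splenic vavCre and Spic_KO shared 23 to 57 rising and 43 to 114 falling genes, and marrow vavCre and Spic_KO 19 to 47 and 39 to 107. The lowest counts came without RPM_d7_Spic_KO replicate 2 for rising and RPM_d7_Spic_WT replicate 1 for falling genes. The vavCre comparisons of spleen and marrow shared 206 to 284 and 162 to 241.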

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

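The tests of this part were planned, except the splits taken after removing the common vavCre effect and their sorting by balance, which were chosen after the result was seen. In RPM_TAM_CreERT2 replicate 4, Sh2d1b1 stood at 22.6, while the other 3 libraries lay between 12.5 and 13.3, so its gap to the nearest was 0.92 of the range. Of 25 measures tested in this way 1 met the limit, and chance alone meets it about 1 time in 20. The cause was not tested.

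The vavCre effect differed between spleen and marrow for 18 genes by the limma-trend interaction test. The log2 differences, spleen minus marrow, were 2.97 for Cd209f, 1.10 for Vcam1, 2.05 for Pf4, 2.03 for Stab1, 2.52 for Cd209g and 1.93 for Timd4, all of which held when any 1 library was left out. Ear2 differed by 3.55, lost without BMM_d7_WT replicate 3 (0.0557) or BMM_d7_vavCre replicate 1 (0.0694). Dmpk (2.59), Gpr34 (-2.17), Fgf1 (5.49) and Ccl7 (3.78) passed with limma adjusted p of 0.0309, 0.0364, 0.0484 and 0.0484, and lost the call under 14 of 23 alternatives each, with adjusted p up to 0.188, 0.161, 0.240 and 0.243. Among the fits that left out 1 library, Dmpk and Fgf1 held only without BMM_d7_vavCre replicate 2 or replicate 3, Gpr34 only without RPM_d7_WT replicate 2, BMM_d7_WT replicate 3 or BMM_d7_vavCre replicate 3, and Ccl7 only without RPM_d7_WT replicate 2 or BMM_d7_vavCre replicate 1. By camera 6 of 27 lists differed, and 0 with an estimated correlation. The 18 became 11 without RPM_d7_WT replicate 1 or BMM_d7_vavCre replicate 1.

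Regrouping the libraries tests how often such counts arise. For the interaction, 5 of 100 drawn splits (of 200 possible) gave at least 18 genes, with 54 as the highest of the others, so chance is not excluded by this count. The 4 other splits called 21, 27, 51 and 54 genes. They are among 8 splits that put 2 more vavCre libraries on the vavCre side in 1 tissue than in the other, which mixes the common vavCre effect into the difference. The 8 had a median of 15 genes, and the other 91 drawn splits called 0, which points to that structure. After removing the common effect the real split gave 21 genes and the highest other 6, with 1 of 100 splits as high, the real one. For the other counts 3 against 3 libraries make 10 splits, too few for a share under 0.05: 835 genes in splenic vavCre (highest other 0), 1182 in marrow vavCre (0), 588 between wild-type tissues (1) and 529 between vavCre tissues (1), with 1 split of 10 as high in each, the real one.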

How the results depend on the processing

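The tests chosen after the results were seen are those on recovered reads (edgeR, DESeq2, limma-voom), library quality weights, the overlaps with 1 library left out and the fit without RPM_d7_Spic_KO replicate 2 and RPM_TAM_CreERT2 replicate 2, the libraries with the highest share of signal in satellite-like genes (2.10 and 2.25%, next 0.802%). The 403 calls of named genes and 6 uncalled results of Pparg and Spic were refitted (409 results). Of the calls 197 were kept under every alternative run for them, and 0 reversed direction. The 1 reversal was the inflammatory list in CreERT2, with a camera adjusted p of 0.593 without RPM_TAM_WT replicate 3, and over all libraries left out its adjusted p ran from 5.1e-07 (without RPM_TAM_WT replicate 1, in the main direction) to 0.593. The cause of the changes below was not tested.

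Splenic vavCre gave 835 genes, and 546 with an absolute log2 change of at least 1, 1367 with only the libraries of the groups compared, 1327 with DESeq2, 1655 with limma-voom and 1488 with library quality weights. Marrow vavCre gave 1182, and 742 with only the libraries of the groups compared. The interaction gave 18, and 11 with no low-value filter, 29 with edgeR, 29 with edgeR and RLE factors and 106 with DESeq2. Wild-type tissues gave 588, and 329 with an absolute log2 change of at least 1, 1010 with DESeq2, 1363 with limma-voom and 964 with library quality weights. The vavCre tissues gave 529, and 1008 with DESeq2. Spic_KO gave 658, and 1834 with DESeq2, 339 with limma-voom and 414 with library quality weights. CreERT2 gave 24, and 5 with no low-value filter, 14 with pseudocount 0.1, 9 with pseudocount 5, 37 with only the libraries of the groups compared (24 up and 13 down), 135 with DESeq2, 40 with limma-voom and 47 without those 2 libraries.

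Leaving out 1 library at a time gave 536 to 649 genes in splenic vavCre, 890 to 1102 in marrow vavCre, 11 to 24 in the interaction, 269 to 665 between wild-type tissues, 271 to 479 between vavCre tissues, 261 to 1972 in Spic_KO and 2 to 18 in CreERT2. A lone library left in a group is assumed to vary like the others. Lists called ranged from 11 to 14 in splenic vavCre, 10 to 13 in marrow vavCre, 4 to 9 in the interaction, 6 to 10 between wild-type tissues, 9 to 13 between vavCre tissues, 6 to 12 in Spic_KO and 3 to 12 in CreERT2. Of the calls of named genes refitted in this way 1999 kept and 467 lost the call.

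With an estimated correlation camera called 5 lists in splenic vavCre (12 with the preset one), 5 in marrow vavCre (13), 0 in the interaction (6), 2 between wild-type tissues (10), 6 between vavCre tissues (11), 0 in Spic_KO (9) and 0 in CreERT2 (9). With fry 2 were called in the interaction and 0 in CreERT2. Overlaps were counted 12 times, and of these counts DESeq2 moved 11 by over 1.5 times, edgeR 4, no low-value filter 6 and the limit on size 2. With 1 library left out 9 to 12 of the 12 overlaps passed, and 6 without RPM_TAM_WT replicate 1.

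Replicate numbers were checked for pairing. Same-numbered libraries hardly deviated together (correlations -0.04 to 0.06), so the numbers are not shown to pair them. In wild-type spleen against marrow, however, same-numbered pairs were all positive (0.048, 0.016 and 0.045). All other pairs there were negative (-0.038 to -0.0032), so pairing of these tissues is not excluded. With the replicate block 784 genes were called in splenic vavCre, 1094 in marrow vavCre, 13 in the interaction, 537 and 494 between tissues, and 219 in Spic_KO. Lists called with the block numbered 12, 13, 7, 11, 12 and 6 in the same order. No paired analysis was possible for CreERT2 because its groups share only number 1.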

Other observations

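The tests chosen after the result was seen are those of a common share, of a single library, of genomic DNA, of more erythroid RNA, and of Ccr3, Fcna and Slpi, while the depth tests and the cell cycle test were written before. Spic_KO and CreERT2 were compared directly, since both groups lie in 1 table. Ccr3, Fcna and Slpi were picked because their values differed, and Fcna lies outside the naming rule. The hypothesis was that Ccr3, Fcna and Slpi respond to Spic and not to Pparg. The difference passed for 3 of 3 genes (Ccr3 -7.58, Fcna -5.90 and Slpi -6.01), which the choice of the genes ensured, so it supports nothing. The series describes few remaining Pparg-deficient cells, so the marrow vavCre values bear on the hypothesis only if the same kinds of cells remain. If so, and if vavCre acts on Pparg, the marrow values of Ccr3 and Slpi argue against the hypothesis. Their changes lay below 0 by more than 2 standard errors in both tissues, with an upper bound of at most -0.64 (Ccr3 in spleen, where its call was lost without RPM_d7_WT replicate 3, 0.0646, or RPM_d7_vavCre replicate 1, 0.0823). Spic itself fell in splenic vavCre, so the splenic falls cannot separate Spic from Pparg. Pparg fell in Spic_KO (-3.33), so the Spic_KO falls cannot separate them either. In marrow, where Spic RNA did not differ detectably, the upper bounds were -1.39 for Ccr3 and -1.68 for Slpi. The marrow Slpi call was lost without BMM_d7_WT replicate 2 (limma adjusted p = 0.0766). In CreERT2 Slpi fell as well (-2.37), while Ccr3 did not change detectably (-0.41, limma adjusted p = 0.804). Ccr3 was picked for this contrast, so its CreERT2 value supports nothing either. Its TAM_WT values also lay far apart, at 991 and 2217. The lectin gene Fcna changed by 0.50 in splenic vavCre (limma adjusted p = 0.0414), -0.33 in marrow vavCre (0.179) and 0.26 in CreERT2 (0.884), and its case stays open. Pparg (-4.20, 0.000378) and Itgad (-4.52, 0.0173) also differed, and 29 genes had a higher and 72 a lower change in Spic_KO than in CreERT2. Age differs between the comparisons (day 7 against adult), so a difference between them may come from age as well as genotype.

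Erythroid and cell cycle genes were lower in vavCre libraries of both tissues. Lower depth was predicted to make the fall shrink when every library was thinned to 4262474 reads. The erythroid median stayed at -1.31 in spleen and -1.51 in marrow. Thinning and rescaling hardly move well-counted genes, so this test leaves depth undecided. A single lower share of erythroid RNA would lower every member alike only if no other cell in the library expresses the members. In marrow the members differed (chi-square p = 0.000558, from Klf1 at -2.43 to Tmcc2 at -0.21), and in spleen they were not shown to differ (0.676). Members that other cells also express would fall less, so the test leaves a common share open in both tissues. Whether cell cycle transcripts come with the erythroid RNA cannot be told apart: over 12 libraries the group-centred r was 0.64 (permutation p = 0.0509) and rho 0.59 (0.107), or 0.46 and 0.35 without BMM_d7_vavCre replicate 3 and BMM_d7_WT replicate 2. Fewer attached or engulfed erythroid cells, the biological difference that the design offers, stays untested.

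Of 11 satellite-like predicted genes, Gm10801 among them, 10 were called higher in Spic_KO (limma, Gm10800 missing with an adjusted p of 0.0520). A single library did not hold the rise, since replicate 1 already lay 3.39 log2 units above the highest Spic_WT library. Genomic DNA in the libraries is a candidate source: at equal depth (692902 reads) olfactory receptor genes with reads numbered 68 and 138 in the Spic_KO libraries against 16, 26 and 16 in Spic_WT. The adult CreERT2 libraries had 112, 202, 90 and 111 against 89 and 26 in TAM_WT, so the same source may add to the CreERT2 differences, where it was not tested further. The first form of this test required replicate 2 to exceed every other library, and CreERT2 replicate 2 broke it with 202, after which the test was changed. No biological explanation was tested.

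Alpha globin genes were higher in CreERT2 by 1.15 on the log2 scale. More erythroid RNA would raise the other markers. Their median was -0.42 and beta globin changed by -0.31. The standard error of that median (0.147) is taken over 19 genes, which are not independent replicates, and not over libraries. The mean log2 level of the whole erythroid list was 7.40 and 8.42 in the TAM_WT libraries and 7.13 to 8.02 in CreERT2. Since the libraries overlap, this test does not decide about erythroid RNA. After thinning to equal reads the change was 1.14. Thinning and rescaling cannot move the ratio of such abundant genes (Hba-a2 held 381627 reads in CreERT2 and 180216 in TAM_WT), so this test decides nothing about depth. Loss of the targeted gene in adults stays untested as a cause.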
